A study of Homo sapiens with 12 samples.

How the data were processed

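RNA sequencing had been done on 12 libraries of human cells labelled as cortical neural progenitor cells (NPCs), which are dividing precursors of neurons and glia, here derived from induced pluripotent stem cells of 2 backgrounds and called line 1 and line 2. Per the labels, the cells had been transfected for 24 h with a set of 4 siRNAs against SF1 or with a non-targeting control siRNA, called siSF1 and siCTRL here. There were 4 groups of 3 libraries, 1 for each line and siRNA. The sequences of the siRNAs are not given in the sources used here. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The labels state RNA integrity numbers above 9.5.

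The values used were the FPKM values (fragments per kilobase and per 1000000 fragments) that the authors deposited as 1 table with a column per library and 48114 genes, with FAST DB gene models and hg38 coordinates per the file headers. The submitters' processing notes name STAR 2.7.5a, Subread 1.5.0 with featureCounts, SAMtools 1.0, Picard 1.119, FastQC 0.11.2 and the hg38 build. Their order, their settings, the use of strand and any filters are not given in the sources used here, so reads of overlapping or antisense genes, of a small RNA and its host gene, or of near-identical copies such as HSPA1A and HSPA1B could have been shared. The table holds no counts. FPKM of short features, with a span under 200 bases, rose in whole steps within each library, and the size of the step gave a denominator of 149.7 to 246 per library, in units of 1000000 reads. All of these values were whole multiples of the step divided by 3, within a tolerance of 0.02, and 91.3% to 92.2% were whole multiples of the step itself. The absolute scale therefore rests on the step being 1 read, and the ratio between libraries does not. Per the labels, each library had 100 in these units, which is under every denominator. If the step is 1 read, the filter of 0.5 FPKM corresponds to 74.9 to 123 reads per kilobase of transcript, and at the depth in the labels it corresponds to 50.0.

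No pair of libraries held identical values. Genes on chromosome Y, XIST and TSIX (145 genes) were left out first. A gene was tested when it had at least 0.5 FPKM in at least 3 libraries, which left 16283 genes, of which 13772 had a symbol and 12528 were protein-coding by a match of name and position to GENCODE 29. The 24985 matches of this kind among all genes gave the gene classes, exon numbers and UTRs. Values were tested as log2(FPKM + 0.1) in limma 3.58.1 (R 4.3.3), with 1 fit of the 4 group means and moderated variances with a trend. The contrasts were the siSF1 effect averaged over both lines, the effect in each line, the difference between the effects (line 2 minus line 1), and the difference between the siCTRL libraries of the lines (line 2 minus line 1). A gene is called at a Benjamini-Hochberg adjusted p under 0.05, 2-sided, over all genes tested. Fold changes are on the log2(FPKM + 0.1) scale, which understates the change of low genes. SF1 itself was also compared within each line by an exact permutation test of 3 against 3 libraries.

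For 33 gene lists (cell type markers, splicing factors, cell cycle, stress, signalling, metabolism, neuronal and disorder genes) limma's camera compared the members with all other genes, with a preset correlation of 0.01 between genes and adjustment over the 31 lists with at least 5 tested members. An estimated correlation and fry were run beside it. The classes of protein-coding genes with a span over 100 kb, single-exon genes, long non-coding RNA genes and pseudogenes were tested in the same way.

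The groups, contrasts, lists, the rule for named genes and all alternatives except 3 were fixed before the data were examined. By that rule the text names SF1 and the 12 genes with the largest increase and the 12 with the largest decrease over both lines, among genes with a symbol, a mean of at least 1 FPKM, a call, and all 3 siSF1 libraries beyond all 3 siCTRL libraries in each line. It names the 6 and 6 of each single line, the 5 and 5 with the largest difference of effect and of siCTRL level between lines, up to 4 members of each list with the smallest p over both lines, and up to 3 members of each marker list with the highest mean FPKM. Pseudogenes, sex-linked genes left out above and genes named only by a clone or identifier are not named. Marker genes under the filter are also given. Some genes that the rule takes are not reported here.

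The alternatives were pseudocounts of 1 and 0.01, no filter or a mean of at least 1 FPKM, median-of-ratios scaling, quantile normalization, rescaling to TPM, variances without a trend or with robust moderation, protein-coding genes only, the replicate number as a block, a fit of the compared groups alone, a limma treat test against a fold of 1.2, voom on whole multiples of the step (recovered for 97.2% of the tested genes), and leaving out each library. The settings without the 2 shallowest libraries and without genes that hold a 7-base word in the 3' UTR, and the estimated correlation for the gene classes, were added after seeing the data.

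The fit was tested on simulated data for 16283 genes with 200 changed genes. For the effect over both lines it called 49.2% of genes changed by 0.25 on the log2 scale, 86.6% at 0.5 and 84.9% at 1, and 3.92% of its calls were unchanged genes. For the difference between effects it called 7.46%, 46.3% and 84.9% at these sizes, and 5.16% of its calls were unchanged genes. For line 1 the shares were 35.8%, 70.2% and 92.4%, for line 2 they were 26.9%, 73.1% and 86.4%, and for the siCTRL difference they were 20.9%, 68.7% and 89.4%. Of 3 lists shifted by 0.2 on the log2 scale, camera, the estimated correlation and fry each found 3, and they called 1, 0 and 2 other lists. The genes were simulated as independent, so this does not show how the tests behave when list members are correlated. Many more genes than the 200 were called in the data, with 7410 over both lines. The adjustment depends on the share of changed genes, so the simulated shares do not carry over as they stand. The recovery of multiples was right for 500 of 500 simulated genes.

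The word search took, per gene, the longest annotated 3' UTR of a coding transcript (12408 tested genes) and regressed the siSF1 effect on the presence of each of 16383 words of 7 bases, with UTR length, base composition, expression level and gene span taken out. In simulations a planted word with a drop of 0.05 on the log2 scale ranked lowest for 8 of 10 words, and with a drop of 0.1 or 0.2 for 10 of 10. Word search and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. Splicing was not analysed here, since the table gives 1 value per gene.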

Results

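Gene expression was measured by RNA sequencing in 12 libraries of human cells labelled as cortical NPCs, from 2 lines, 24 h after transfection with siRNAs against SF1 or with a non-targeting siRNA. SF1 is a splicing factor that binds the branch point of introns early in spliceosome assembly. Each of the 4 groups had 3 libraries, and the step of the FPKM values gave a denominator of 149.7 to 246 per library, in units of 1000000 reads, where the labels state 100 for each. The shallowest libraries were siSF1 replicate 1 of line 2 (149.7) and siSF1 replicate 2 of line 1 (155). Both also stood apart from their groups, the former on principal component 3 (34.6) and the latter on component 4 (-37.0). On component 3 siSF1 replicate 3 of line 2 lay apart the other way (-20.5, against -1.70 for replicate 2). The first component held 66.4% of the variance and separated the lines, and the second held 7.95% and separated siSF1 from siCTRL in both lines. Pearson correlations between replicates lay between 0.977 and 0.985.

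SF1 mRNA was lower in every siSF1 library than in every siCTRL library. The gene (GSHG0007868 in the table) lies on the minus strand of chromosome 11, from 64764606 to 64778769 in hg38. In line 1 its level was 65.6 ± 2.16 FPKM (SD, n = 3) with siCTRL and 15.9 ± 1.39 with siSF1, which is 24.2% of the control. In line 2 it was 79.1 ± 0.420 FPKM (SD, n = 3) with siCTRL and 16.8 ± 2.68 with siSF1, which is 21.2% of the control. Over both lines SF1 fell by 2.14 on the log2 scale (SE 0.07, limma adjusted p = 2.3e-08). The exact permutation test gave p = 0.1 in each line, the smallest value that 3 against 3 libraries allow.

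**Figure D1:**
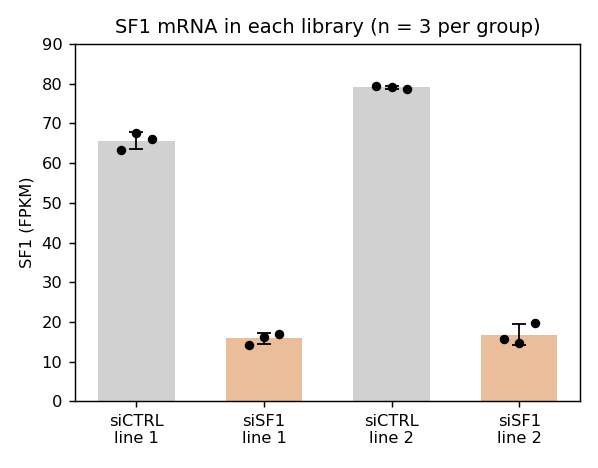
SF1 level in FPKM (y axis) in each library (points) of the 4 groups (x axis), with bars for the mean and error bars for the SD of 3 libraries. The siSF1 libraries lie between 14.3 and 19.8 FPKM, and the siCTRL libraries between 63.3 and 79.4 FPKM.

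The first comparison asked which genes changed with the SF1 knockdown over both lines. LIN28A, an RNA-binding protein that blocks maturation of the let-7 microRNAs, had the largest increase of the named genes, by 1.65 on the log2 scale (SE 0.06, limma adjusted p = 4.5e-08). Its level went from 3.07 ± 0.272 to 12.7 ± 0.635 FPKM in line 2 (SD, n = 3), and in line 1 from 0.0356 ± 0.00946 to 0.230 ± 0.0107 FPKM, which is under the 0.5 FPKM of the filter, where the scale with its pseudocount understates a change. GNRH2, a gonadotropin-releasing hormone, rose by 1.19, TXNIP, an inhibitor of thioredoxin, by 1.11, and IGDCC3, an immunoglobulin superfamily member, by 1.11. POLR3G, a subunit of RNA polymerase III, rose by 0.97. It went from 20.3 ± 0.508 to 38.6 ± 4.26 FPKM in line 2. FIGNL2 (0.98), DOK3 (0.93), HGFAC (0.89), the growth factor VEGFD (0.87), the palmitoyltransferase ZDHHC12 (0.87), the apical polarity gene CRB2 (0.86) and the actin-bundling gene FSCN2 (0.85) also rose. The increase was 1.00 for LIN28A, 0.64 for FIGNL2, 0.45 for HGFAC, 0.56 for CRB2 and 0.52 for FSCN2 with a pseudocount of 1. The limma adjusted p of these risers lay between 4.5e-08 and 7.8e-05. Each was higher in 6 of 6 siSF1 libraries than in the siCTRL libraries of its line, which the rule for named genes requires.

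Besides SF1, the largest decreases were those of ARHGDIB, KIAA1191 and SPP1, which encodes the secreted phosphoprotein osteopontin. ARHGDIB fell by 2.11 (SE 0.07), from 13.9 ± 0.660 to 3.08 ± 0.0664 FPKM in line 1 and from 8.03 ± 0.775 to 1.84 ± 0.316 FPKM in line 2. KIAA1191 fell by 2.06 (SE 0.03) and SPP1 by 1.92 (SE 0.06), with limma adjusted p of 2.4e-10 and 2.3e-08. VAT1L (-1.67), INHBA (-1.54), a subunit of activin A, the BCL2 family member BCL2A1 (-1.48), CYTL1 (-1.47), PHLDA2 (-1.42), the receptor ERBB3 (-1.40) and RPUSD4 (-1.32) fell as well, with limma adjusted p up to 5.1e-05. The change was -1.08 for VAT1L, -0.86 for BCL2A1 and -0.79 for ERBB3 with a pseudocount of 1. Of the 12 genes with the largest decreases by the rule for named genes, SF1 included, 7 (among them ARHGDIB, KIAA1191, SPP1, VAT1L, INHBA and RPUSD4) have an annotated 3' UTR that holds the 7-base word GAGAACA, a word picked after its values were seen. None of the 11 named risers with an annotated 3' UTR holds it.

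The word also occurs once in the SF1 mRNA, at bases 475 to 481 of 3470, in the coding sequence of exon 2 (chromosome 11, 64776515 to 64776521 in hg38, minus strand), within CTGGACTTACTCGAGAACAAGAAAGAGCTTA. Among 1832 tested genes with the word in the 3' UTR, 794 were called lower (43.3%) and 290 higher (15.8%), with a median change of -0.09 on the log2 scale. Among 10576 genes without it, 2422 were called lower (22.9%) and 3024 higher (28.6%), with a median of 0.02.

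**Figure D2:**
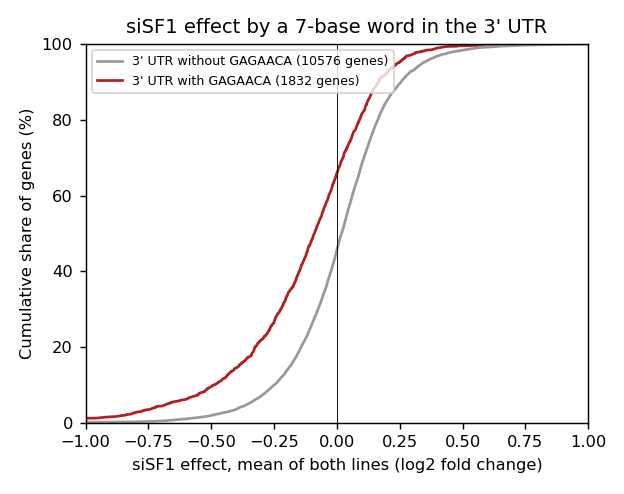
Cumulative share of genes in percent (y axis) against the siSF1 effect averaged over both lines in log2 fold change (x axis), for 1832 genes with GAGAACA in the 3' UTR (red) and 10576 genes without it (grey). The red curve lies to the left, with medians of -0.09 and 0.02.

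**Figure D3:**
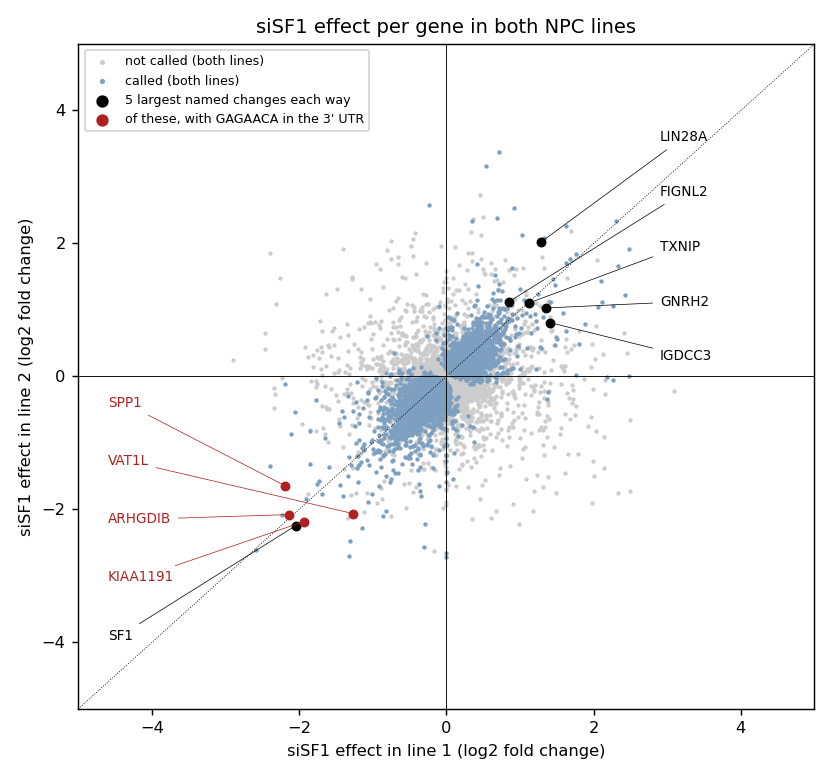
siSF1 effect in line 1 (x axis) and line 2 (y axis) as log2 fold change, with a point for each of 16283 tested genes and the 5 named genes with the largest increase and the 5 with the largest decrease over both lines labelled. Labelled genes with GAGAACA in the 3' UTR are red, which are ARHGDIB, KIAA1191, SPP1 and VAT1L among those that fell.

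In all, limma called 7410 of 16283 genes over both lines, 3781 higher and 3629 lower, and the median size of a called change was 0.23 on the log2 scale. More genes were called lower than higher after median-of-ratios scaling (3860 and 3538) or rescaling to TPM (3894 and 3151), so no majority is read from these counts. Changes of at least 2-fold were found for 51 genes that rose and 75 that fell. Against a fold of 1.2 instead of any change, the limma treat test called 800 genes.

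Among the gene lists, p53 target genes moved together most clearly. Of 33 members 26 rose and 1 fell (26 and 1 adjusted over the list alone), with a median of 0.26, and limma's camera gave an adjusted p of 1.3e-09 (adjusted p = 0.00974 with an estimated correlation). SESN2 rose by 0.57, the cell cycle inhibitor CDKN1A by 0.56, SESN1 by 0.41 and ZMAT3 by 0.41. Of 41 genes of G1/S and DNA replication, 29 fell and 3 rose (30 and 3 adjusted over the list alone), with a median of -0.18 and a camera adjusted p of 2.3e-06 (adjusted p = 0.751 with an estimated correlation). CDC6, which loads the replicative helicase and whose 3' UTR holds the word, fell by 0.46, GINS2 fell by 0.41, and the helicase subunits MCM5 and MCM7 fell by 0.37 and 0.27. Of 53 cytosolic ribosomal protein genes, 35 rose and 1 fell (38 and 2 adjusted over the list alone), with a median of 0.13 (0.077 after quantile normalization) and a camera adjusted p of 4.5e-07 (adjusted p = 0.751 with an estimated correlation). RPL15 rose by 0.20, RPS15 by 0.18 and RPL4 by 0.17. Of 41 nuclear-encoded respiratory chain genes, 21 rose and 2 fell (21 and 2 adjusted over the list alone), with a camera adjusted p of 0.0020 (adjusted p = 0.751 with an estimated correlation). UQCRFS1 rose by 0.19 and SDHC by 0.17. NDUFS1, whose 3' UTR holds the word, fell by 0.17.

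Of 26 hnRNP genes, which encode abundant RNA-binding proteins of the nucleus, 14 fell and 1 rose (15 and 2 adjusted over the list alone), with a median of -0.08 and a camera adjusted p of 0.0036 (adjusted p = 0.751 with an estimated correlation). HNRNPD fell by 0.80, HNRNPDL, whose 3' UTR holds the word, by 0.69, and HNRNPH1 by 0.18, while PTBP2, a neuronal splicing regulator, rose by 0.69. Of 25 SR proteins and their kinases, 13 fell and 3 rose (13 and 3 adjusted over the list alone), but the list did not pass (camera adjusted p = 0.0558). TRA2A fell by 0.31, SRSF1 by 0.23, SRSF6, whose 3' UTR holds the word, by 0.17 and SRSF5 by 0.16. Of 31 early spliceosome and U2 snRNP factors, 13 fell and 7 rose (13 and 7 adjusted over the list alone; camera adjusted p = 0.352). SNRPA1 fell by 0.37, RBM10 by 0.33 and U2AF2, the partner of SF1 at the 3' end of introns, by 0.24, and SF3B3 rose by 0.36. Nonsense-mediated decay and exon junction factors (4 higher and 3 lower of 18) and snoRNA host genes (7 and 2 of 16) did not pass, with camera adjusted p of 0.967 and 0.318 and the same counts adjusted over the list alone.

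Immediate early genes, which respond fast to growth signals, fell in 10 of 26 cases and rose in 0 (10 and 0 adjusted over the list alone), with a median of -0.20 and a camera adjusted p of 0.0037 (adjusted p = 0.339 with an estimated correlation). EGR2, whose 3' UTR holds the word, fell by 0.77, KLF2 by 0.72, MYC by 0.34 and SPRY2 by 0.24. Of 41 genes of G2/M and mitosis, 12 fell and 0 rose (4 and 0 adjusted over the list alone), with a median of -0.11 and a camera adjusted p of 0.00996 (adjusted p = 0.971 with an estimated correlation). NDC80 fell by 0.33, CENPF by 0.24, KIF11 by 0.23, and MKI67, whose 3' UTR holds the word, by 0.20. The G2/M list lost its call without siCTRL replicate 3 of line 1 (median -0.074, adjusted p = 0.138) or without siSF1 replicate 3 of line 2 (adjusted p = 0.0693).

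**Figure D4:**
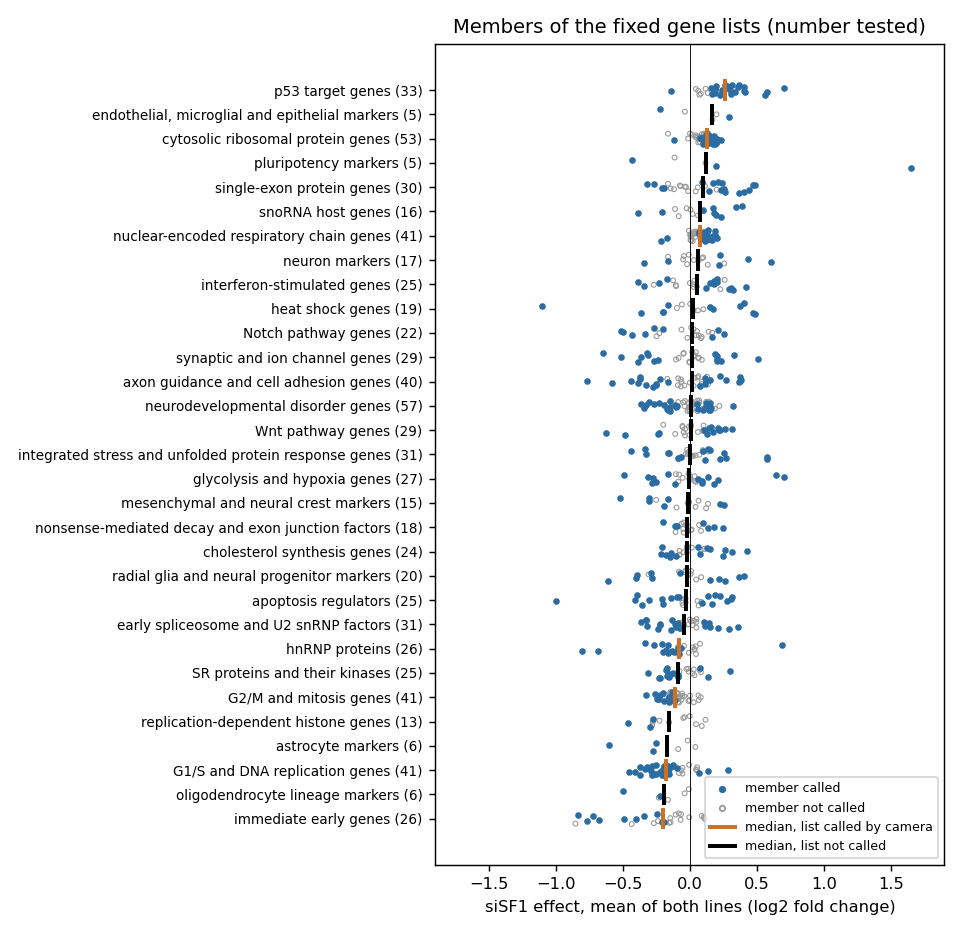
siSF1 effect averaged over both lines in log2 fold change (x axis) for each tested member (points, filled where called) of the 31 tested gene lists (y axis, with the number of members tested), and the median of each list as a bar. The medians of the 7 lists that camera called are orange, from 0.26 for p53 target genes to -0.20 for immediate early genes.

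Progenitor and cell type markers moved in both directions. PAX6, HES5, OTX2, EMX2 and FEZF2, markers of cortical progenitors, lay under the filter in every library and were not tested. Of 20 radial glia and neural progenitor markers tested, 6 fell and 5 rose (8 and 5 adjusted over the list alone; camera adjusted p = 0.703). The intermediate filament gene NES fell by 0.61, SLC1A3 by 0.40, the RNA-binding protein MSI1, whose 3' UTR holds the word, by 0.39, TNC by 0.29 and PROM1 by 0.28. VIM had a level of 3641 FPKM and a value of 0.15, which was 0.00 after quantile normalization, and PTN (441 FPKM) had a value of 0.01. Of 17 neuron markers 4 rose and 2 fell (camera adjusted p = 0.554), with SYP at 0.61 (0.34 with a pseudocount of 1), INA at 0.43, DCX, whose 3' UTR holds the word, at 0.21 and GAP43 at -0.17. Of 6 astrocyte markers 3 fell, CD44 by 0.60, S100B by 0.28 and FGFR3 by 0.26 (camera adjusted p = 0.147). Of 6 oligodendrocyte lineage markers 2 fell, both with the word in the 3' UTR, among them PDGFRA by 0.22 (camera adjusted p = 0.147). The call of PDGFRA ended without the 2 shallowest libraries (adjusted p = 0.0531). Of 15 mesenchymal and neural crest markers 2 rose, COL1A2 by 0.26 and COL3A1 by 0.23, and 5 fell, among them TAGLN by 0.52, TFAP2A, whose 3' UTR holds the word, by 0.31 and POSTN by 0.30 (5 lower and 3 higher adjusted over the list alone; camera adjusted p = 0.783). Pluripotency markers (2 higher and 1 lower of 5) and endothelial, microglial and epithelial markers (1 and 1 of 5) gave camera adjusted p of 0.741 and 0.789. Among intermediate progenitor and neurogenesis genes, of which 3 were tested, BTG2 rose by 0.70 and HES6 fell by 0.34. For the marker lists not given such counts, those adjusted over the list alone were the same.

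The remaining lists did not pass camera over both lines. Notch pathway genes (3 higher and 6 lower of 22; adjusted p = 0.703) included RBPJ, the DNA-binding partner of Notch, which fell by 0.51. Wnt pathway genes (10 and 4 of 29; adjusted p = 0.741) included LEF1, which fell by 0.49. Heat shock genes (6 and 5 of 19; adjusted p = 0.741) included the small heat shock protein CRYAB, which fell by 1.10 (-0.62 with a pseudocount of 1). Genes of the integrated stress and unfolded protein response (9 and 7 of 31; adjusted p = 0.866) included the chaperone CALR, which fell by 0.44. Apoptosis regulators (8 and 10 of 25; adjusted p = 0.789) included CASP8, which rose by 0.32, and BIRC2, which fell by 0.40. Glycolysis and hypoxia genes (8 and 7 of 27; adjusted p = 0.923) included the glucose transporter SLC2A3, which rose by 0.70. Cholesterol synthesis genes (8 and 6 of 24, 10 and 6 adjusted over the list alone; adjusted p = 0.866) included MSMO1, which rose by 0.43. Interferon-stimulated genes had 10 higher and 4 lower of 25 (adjusted p = 0.703). Neurodevelopmental disorder genes (11 and 16 of 57, 12 and 17 adjusted over the list alone; adjusted p = 0.741) included CTNNB1, which fell by 0.23. Synaptic and ion channel genes had 7 higher and 8 lower of 29 (adjusted p = 0.919). Axon guidance and cell adhesion genes (11 and 12 of 40, 11 and 13 adjusted over the list alone; adjusted p = 0.783) included PLXNA4, which fell by 0.77 (-0.36 with a pseudocount of 1). Replication-dependent histone genes (0 and 3 of 13) and single-exon protein genes (13 and 4 of 30) gave adjusted p of 0.317 and 0.318, and 0 of 13 mitochondrially encoded genes were tested. Counts adjusted over the list alone were the same for the other lists of this paragraph. The median and the mean of the members differed in sign for the Notch, cholesterol, glycolysis, synaptic, neurodevelopmental disorder and axon guidance lists and for the nonsense-mediated decay list.

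Of 2540 protein-coding genes with a span over 100 kb, 861 fell and 489 rose (883 and 505 adjusted over the list alone), and of 224 single-exon protein-coding genes 34 fell and 96 rose (35 and 98 adjusted over the list alone), each with a camera adjusted p of 0.0068 (adjusted p = 0.692 with an estimated correlation). The call of the single-exon class ended without a filter on low values (adjusted p = 0.272). Across 12528 protein-coding genes, which are not independent replicates, Spearman's rank correlation of the effect with span was -0.171, and it was -0.0886 in line 1 and -0.224 in line 2. Long non-coding RNA genes (92 higher and 65 lower of 418, 88 and 61 adjusted over the list alone) and pseudogenes (40 and 37 of 258, 33 and 32 adjusted over the list alone) gave camera adjusted p of 0.513 and 0.771.

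**Figure D5:**
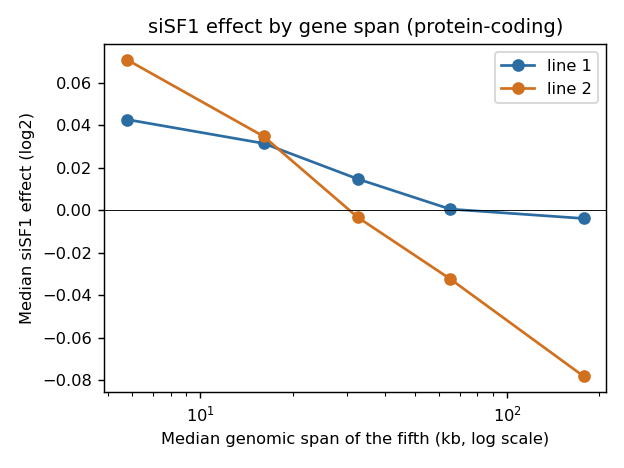
Median siSF1 effect in log2 fold change (y axis) of protein-coding genes in 5 groups of equal size ordered by genomic span, against the median span of the group in kb (x axis, log scale), for line 1 (blue) and line 2 (orange). In line 2 the median went from 0.07 in the shortest group to -0.08 in the longest, and in line 1 from 0.04 to -0.00.

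The second comparison took each line by itself. In line 1 limma called 4552 genes, 2388 higher and 2164 lower, and in line 2 it called 5836, 2710 higher and 3126 lower. Which direction had more calls turned with the scaling, to 1995 higher and 2462 lower in line 1 after median-of-ratios scaling, 1874 and 2229 in line 1 after rescaling to TPM, and 3153 and 2879 in line 2 after quantile normalization. In line 1 IGDCC3 (1.41), GNRH2 (1.35) and LIN28A (1.29) rose most among the named genes, where LIN28A had 0.25 with a pseudocount of 1 and 2.42 with 0.01. Besides SF1 the deepest falls included SPP1 (-2.20), ARHGDIB (-2.14) and DKK2 (-1.64), a secreted Wnt modulator whose 3' UTR holds the word. In line 2 LIN28A rose by 2.02, and the small RNA genes MIR103A2 and MIR3661 by 1.29 and 1.08. Both are short features whose reads could not be told from longer RNAs here. MIR3661 lost its call without siCTRL replicate 1 (adjusted p = 0.0881), siCTRL replicate 2 (0.0596), siSF1 replicate 1 (0.0536) or siSF1 replicate 2 (0.0856) of line 2, and with no filter on low values (0.0571). The largest falls in line 2 besides SF1 included KIAA1191 (-2.18), BCL2A1 (-2.09, and -1.03 with a pseudocount of 1) and VAT1L (-2.06). Among p53 target genes 25 of 33 rose in line 1 and 23 in line 2 (26 and 24 adjusted over the list alone), with camera adjusted p of 2.1e-09 and 1.5e-08 (adjusted p = 0.0105 and 0.0143 with an estimated correlation). Of the genes called in both lines, 1535 rose in both (397 for independent lists), 1637 fell in both (415) and 74 went opposite ways (819), and the lines share no control library. Across genes the log2 fold changes of the lines had a Pearson r of 0.417 and a Spearman rank correlation of 0.603.

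The third comparison asked where the effect differed between lines. SLC29A1, a nucleoside transporter whose 3' UTR holds the word, fell by 0.71 in line 1 and rose by 0.35 in line 2, a difference of 1.06 (SE 0.07, limma adjusted p = 0.00049). ALDH1A3, an enzyme of retinoic acid synthesis, went the other way, by 0.32 in line 1 and -0.75 in line 2 (difference -1.08, SE 0.08, limma adjusted p = 0.00049). GREM1, a BMP antagonist whose 3' UTR holds the word, fell by 1.33 in line 1 and by 0.30 in line 2, and the opioid precursor PENK changed by -0.27 and 0.61. FREM1 changed by 0.29 in line 1 and -0.60 in line 2, and the G protein subunit GNA14 by -0.36 and 0.55. Among genes named for the effect over both lines, IGDCC3 rose more in line 1 (difference -0.60, and -0.39 with a pseudocount of 1; limma adjusted p = 0.0061), a call that ended without the 2 shallowest libraries (0.0537). LIN28A had a difference of 0.74 on the log2(FPKM + 0.1) scale (limma adjusted p = 0.0126), but with a pseudocount of 0.01 it was -0.36 (adjusted p = 0.3995, and 1.7e-05 to 0.695 over its other settings). It was 1.51 with a pseudocount of 1, 1.17 after quantile normalization and 0.15 after rescaling to TPM. In mean FPKM LIN28A rose 6.46-fold in line 1 and 4.15-fold in line 2, so its order between the lines rests on the scale. In all, 385 genes were called for the difference, 87 with the higher value in line 2 and 298 in line 1. The calls of GREM1, GNA14 and PENK ended without the 2 shallowest libraries (adjusted p = 0.0537, 0.0627 and 0.0547). Without these libraries 65 genes were called. Leaving out single libraries gave 213 genes without siCTRL replicate 1 of line 1, 206 without its siCTRL replicate 3, 205 and 198 without its siSF1 replicates 2 and 3, 156 and 190 without siCTRL replicates 1 and 2 of line 2, and 208, 242 and 852 without its siSF1 replicates 1, 2 and 3.

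The siSF1 effect on radial glia and neural progenitor markers was lower in line 2 than in line 1 (median difference -0.23, camera adjusted p = 0.0025; adjusted p = 0.587 with an estimated correlation). The median was -0.15 with a pseudocount of 1 and -0.13 with no filter on low values. For the difference 3 of 20 were called lower and 0 higher (8 and 0 adjusted over the list alone). The effect on protein-coding genes with a span over 100 kb was also lower in line 2, with a median difference of -0.075 (-0.045 after quantile normalization). Of 2540 such genes 138 were called lower and 17 higher (234 and 43 adjusted over the list alone; camera adjusted p = 8.5e-06; adjusted p = 0.225 with an estimated correlation).

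The fourth comparison set the siCTRL libraries of the lines side by side. H19, an imprinted long non-coding RNA, was listed at 0.0132 ± 0.00412 FPKM in line 1 and 120 ± 3.13 in line 2 (SD, n = 3; limma adjusted p = 3.4e-12). TNFRSF11B, a decoy receptor of RANKL, was higher in line 2 by 5.80 on the log2 scale, the collagen gene COL22A1 by 5.73 and OLIG1, a transcription factor of the oligodendrocyte lineage, by 5.59. ZNF667-AS1 was listed at 0 in the 3 siCTRL libraries of line 1 and had 5.50 ± 0.228 FPKM in line 2. Higher in line 1 were FMOD, a collagen-binding proteoglycan (-6.21), RWDD2B (-5.33), the neuropeptide gene NTS (-5.12), TNMD, a tendon gene (-5.04), and PAX8-AS1 (-4.90), with limma adjusted p up to 1.9e-09. These sizes depend on the scale, since with a pseudocount of 1 they were 2.65 for COL22A1, 2.56 for OLIG1, -2.67 for RWDD2B and -3.03 for PAX8-AS1. They were 8.86 for COL22A1 and 8.49 for OLIG1 with 0.01, and 10.52 for OLIG1 with voom. The median of all genes was 0.14 on the log2 scale, and it was 0.02 after median-of-ratios scaling and -0.01 after quantile normalization. List medians are to be read against it. limma called 10625 genes, 7088 higher in line 2 and 3537 higher in line 1 (66.7% higher). The split was 5186 and 5022 after median-of-ratios scaling (50.8%) and 4966 and 5298 after quantile normalization (48.4%).

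Of 15 mesenchymal and neural crest markers 12 were higher in line 1 and 3 in line 2 (median -1.02, camera adjusted p = 8e-05; adjusted p = 0.154 with an estimated correlation). The pluripotency markers tested were higher in line 2 in 5 of 5 cases, with a median of 2.21 (0.092 with no filter on low values). For them camera gave an adjusted p of 0.0025 (0.159 with an estimated correlation). LIN28A, 1 of the 5, passed the filter only through line 2. The pluripotency markers POU5F1, NANOG, ZFP42, TDGF1, PRDM14, UTF1 and ESRG were not tested, with at most 0.0279 FPKM (NANOG) in any library. No difference in pluripotency between the lines is read from this list. Genes of G1/S and DNA replication were higher in line 2 in 37 of 41 cases (median 0.50, adjusted p = 1.9e-05 by camera; adjusted p = 0.691 with an estimated correlation). hnRNP genes were higher in line 2 in 24 of 26 cases (median 0.32, and 0.19 after median-of-ratios scaling; camera adjusted p = 0.00077; adjusted p = 0.650 with an estimated correlation). Interferon-stimulated genes were higher in line 2 in 19 of 25 cases (median 0.76, and 0.46 with a pseudocount of 1; camera adjusted p = 0.0094; adjusted p = 0.154 with an estimated correlation; 0.0959 with a mean of at least 1 FPKM). Genes of the integrated stress and unfolded protein response were higher in line 1 in 18 of 31 (median -0.33, camera adjusted p = 0.00077; adjusted p = 0.442 with an estimated correlation). Genes of G2/M and mitosis were higher in line 2 in 30 of 41 cases (median 0.41, camera adjusted p = 0.0052; adjusted p = 0.870 with an estimated correlation). Early spliceosome factors were higher in 24 of 31 (median 0.22, camera adjusted p = 0.0126; adjusted p = 0.351 with an estimated correlation), a call lost after median-of-ratios scaling (median 0.096, adjusted p = 0.119). Their median was 0.15 after quantile normalization. Synaptic and ion channel genes were higher in 21 of 29 (median 0.61, camera adjusted p = 0.0199; adjusted p = 0.712 with an estimated correlation), a call lost with a mean of at least 1 FPKM (median 0.34, adjusted p = 0.122) or without genes that hold GAGAACA in the 3' UTR (median 0.38, adjusted p = 0.0764). Their median was 0.31 with a pseudocount of 1 and 0.35 after quantile normalization. The setting without genes that hold GAGAACA takes out 4 of the 29 synaptic members. The siCTRL libraries had no siRNA against SF1, so this loss of the call says nothing about a seed. Counts adjusted over the list alone differed for G1/S genes, with 2 instead of 1 higher in line 1, and were the same for the other lists named here. Several markers of the cortical progenitors that the labels name lay under the filter in every library, while 20 radial glia and neural progenitor markers passed it. The highest FPKM of any library was 0.0456 for PAX6, 0.0427 for HES5, 0.0806 for OTX2, 0.161 for EMX2 and 0.00440 for FEZF2. GFAP reached 0.0376. At the same time the mean over all libraries was 640 FPKM for COL1A2, 443 for LUM, 427 for POSTN and 167 for COL3A1.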

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

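In this part the setting without the 2 shallowest libraries was chosen only after the depths were seen, and the folds of mean FPKM and the groupings with the siSF1 effect taken out only after the results were seen. The results given here are those for which a limma or camera test found that the siSF1 effect differed between the lines, and differences are line 2 minus line 1. ANKRD1, an ankyrin repeat gene, changed by -0.76 in line 1, with a value of 0.38 that did not pass in line 2, a difference of 1.14. The differences of SLC29A1, GREM1, GNA14 and PENK were 1.06, 1.03, 0.91 and 0.88. Those of ALDH1A3, SNORA51, SERPINA3, GRM3 and FREM1 were -1.08, -1.05, -1.004, -0.96 and -0.89. SERPINA3, a secreted protease inhibitor, changed by 0.34 in line 1 and -0.67 in line 2, and the small nucleolar RNA gene SNORA51 by 0.47 and -0.58. GRM3, a glutamate receptor, rose by 0.67 in line 1 and had a value of -0.29 in line 2 that did not pass. Among genes named for the effect over both lines, the differences were 0.74 for LIN28A, -0.60 for IGDCC3, 0.55 for SPP1 and -0.80 for VAT1L. That of LIN28A turned to -0.36 with a pseudocount of 0.01, and in mean FPKM LIN28A rose 6.46-fold in line 1 and 4.15-fold in line 2, so no order of the lines is read from it. It was 1.51 with a pseudocount of 1, 1.17 after quantile normalization and 0.15 after rescaling to TPM. The difference of VAT1L was -1.34 with a pseudocount of 1, -0.48 with 0.01 and -0.44 with voom. Its mean FPKM in siSF1 libraries was 0.311 of that in siCTRL libraries in line 1 and 0.232 in line 2, a log2 difference of -0.42, so its size rests on the scale. With a pseudocount of 1 the difference was also 0.48 for GNA14, -0.55 for GRM3 and -0.39 for IGDCC3.

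The call of ANKRD1 ended on leaving out any of 10 of the 12 libraries. The limma adjusted p was 0.0798, 0.0772 and 0.0905 without siCTRL replicates 1, 2 and 3 of line 1, and 0.0827, 0.0740 and 0.0756 without its siSF1 replicates 1, 2 and 3. It was 0.101, 0.0944 and 0.0528 without siCTRL replicates 1, 2 and 3 of line 2, and 0.0621 without its siSF1 replicate 2. The call of SNORA51 ended for 8 of the 12. Its limma adjusted p was 0.0508, 0.0632 and 0.0716 without siCTRL replicates 1, 2 and 3 of line 1 and 0.0522 without siSF1 replicate 3 of that line. It was 0.0657 and 0.0602 without siCTRL replicates 2 and 3 of line 2, and 0.0542 and 0.0673 without siSF1 replicates 1 and 2 of that line. The call of SPP1 ended for 11 of the 12. Its limma adjusted p was 0.0892, 0.0862 and 0.102 without siCTRL replicates 1, 2 and 3 of line 1, and 0.0725, 0.0516 and 0.0844 without siSF1 replicates 1, 2 and 3 of that line. It was 0.114, 0.0842 and 0.0721 without siCTRL replicates 1, 2 and 3 of line 2, and 0.0835 and 0.0953 without siSF1 replicates 1 and 2 of that line. GRM3 lost its call without siCTRL replicate 1 of line 2 (limma adjusted p = 0.0550), and so did VAT1L (0.05).

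Without the 2 shallowest libraries limma gave an adjusted p of 0.0582 for ANKRD1, 0.0884 for SNORA51, 0.102 for GRM3, 0.0537 for GREM1, 0.0627 for GNA14, 0.0547 for PENK, 0.0986 for LIN28A, 0.0537 for IGDCC3, 0.0847 for SPP1 and 0.0795 for VAT1L. Rescaling to TPM ended the calls of LIN28A (0.695), VAT1L (0.0663), ANKRD1 (0.0517) and SPP1 (0.0504). Those of VAT1L (0.327) and SNORA51 (0.117) ended with voom, and those of LIN28A (0.3995) and VAT1L (0.142) with a pseudocount of 0.01. With no filter those of SPP1 (0.0921), ANKRD1 (0.0817) and SNORA51 (0.0582) ended. SPP1 also lost its call with quantile normalization (0.0633) or variances without a trend (0.0574). The replicate number as a block within lines ended the calls of GREM1, GNA14, SNORA51, SPP1, VAT1L and SERPINA3 (limma adjusted p = 0.0695 for SERPINA3).

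Among gene groups, the median difference was -0.23 for radial glia and neural progenitor markers and -0.075 for protein-coding genes with a span over 100 kb, and both kept their camera call without any single library. It was -0.20 for oligodendrocyte lineage markers, -0.15 for synaptic and ion channel genes, -0.10 for axon guidance and cell adhesion genes, -0.070 for neurodevelopmental disorder genes, 0.082 for G2/M and mitosis genes and 0.051 for nuclear-encoded respiratory chain genes. The median was -0.15 with a pseudocount of 1 and -0.13 with no filter for radial glia markers, and after quantile normalization it was -0.045 for long genes and -0.094 for synaptic genes. The camera adjusted p of these groups was 0.0025 for radial glia markers, 8.5e-06 for long genes, 0.0312 for oligodendrocyte markers, 0.0165 for synaptic genes, 0.0393 for axon guidance genes, 0.0195 for disorder genes, 0.0083 for G2/M genes and 0.0025 for respiratory chain genes. With an estimated correlation none passed, with adjusted p from 0.225 for long genes to 0.903 for G2/M genes.

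Without the 2 shallowest libraries the camera adjusted p was 0.0936 for oligodendrocyte markers, 0.0804 for synaptic genes, 0.204 for axon guidance genes and 0.128 for G2/M genes. The call of oligodendrocyte markers also ended with a pseudocount of 0.01 (0.0871), a mean of at least 1 FPKM (0.116), TPM (0.0515) or voom (0.0607), and that of axon guidance genes with a pseudocount of 1 (0.0968) or a mean of at least 1 FPKM (0.0994). Without siSF1 replicate 2 of line 2 the camera adjusted p was 0.0891 for oligodendrocyte markers, 0.106 for synaptic genes, 0.115 for axon guidance genes, 0.115 for disorder genes, 0.0744 for G2/M genes and 0.0891 for respiratory chain genes. Oligodendrocyte markers also lost the call without siCTRL replicate 2 of line 1 (0.0630), siCTRL replicate 2 of line 2 (0.0637) or siSF1 replicates 1 or 3 of line 2 (0.0604 and 0.0543). G2/M genes lost it without siCTRL replicate 3 of line 1 (0.755), siSF1 replicate 1 of line 1 (0.143) or siSF1 replicate 1 of line 2 (0.0604). Their median difference was 0.0033 without siCTRL replicate 3 and 0.049 without siSF1 replicate 1 of line 1, and 0.043 without the 2 shallowest libraries. It was 0.17 without siCTRL replicate 2 and 0.13 without siSF1 replicate 3 of line 1, where the call held. Disorder genes lost the call without siSF1 replicate 3 of line 1 (0.0870). Axon guidance genes lost it without siCTRL replicate 1 (0.0587) or siSF1 replicates 2 or 3 (0.0870 and 0.0555) of line 1, and without siCTRL replicates 2 or 3 (0.0675 and 0.0712) or siSF1 replicate 1 (0.138) of line 2, and their median was -0.16 without siSF1 replicate 3 of line 2, where the call held.

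In all 385 genes were called for the difference between lines. Groupings that mix the siRNAs of a line put the siSF1 effect itself into the spread or the contrast, so the effect over both lines was first taken out of each library. Of 100 such splits of the libraries within lines, 1 called as many genes, the real one (385, highest other 3). That share is under 0.05, but it bears only on the spread between these libraries. They may be technical replicates, so chance between cultures is not excluded. With the effect left in, 2 of 100 groupings called as many genes, which decides nothing about chance. The other of these called 1030 genes and gave 4 libraries of line 1 and 0 of line 2 another siRNA label, so that it carried -0.333 of the effect in line 1 and 1 times the effect in line 2. Exchanging the siRNA labels of line 2 alone, which was not among the groupings drawn, turns the siSF1 effect itself into a difference between lines and gives 7410 genes.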

How the results depend on the processing

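The settings without the 2 shallowest libraries and without genes that hold GAGAACA in the 3' UTR, and the estimated correlation for gene classes, were chosen only after the data were seen. SF1 stayed between -2.17 and -2.08 on the log2 scale over the other settings, and between -2.21 and -2.10 on leaving out each library. Apart from limma treat, the counts were 6134 to 7907 genes over both lines (6705 to 7808 on leaving out each library), 3052 to 4697 in line 1 (3332 to 5340), 4365 to 6098 in line 2 (4609 to 6283), 8817 to 14299 between siCTRL libraries (9918 to 11066) and 2115 to 3352 called the same way in both lines (2409 to 3493). Without genes that hold the word, which does not remove other seeds, fewer genes were tested, and 6229 were called over both lines, 3710 in line 1 and 4820 in line 2. Against a fold of 1.2, a stricter null, limma treat called 800 genes over both lines, 349 in line 1, 765 in line 2, 7 for the difference between lines, 5559 between siCTRL libraries and 221 the same way in both lines.

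The count for the difference between lines, 385, was 630 with protein-coding genes only (365 shared) and 65 without the 2 shallowest libraries (62 shared). On leaving out each library it lay between 156 and 852, with 213 and 206 without siCTRL replicates 1 and 3 of line 1, 205 and 198 without its siSF1 replicates 2 and 3, 156 and 190 without siCTRL replicates 1 and 2 of line 2, and 208, 242 and 852 without its siSF1 replicates 1, 2 and 3. The cause was not tested. Of the gene lists, 7 with camera, 1 was called with an estimated correlation and 13 with fry, 6 of them shared with camera. Of the gene classes, 2 with camera, 1 was called with no filter on low values and 0 with an estimated correlation (0 at an unadjusted p under 0.05), and the cause was not tested. VIM went to 0.00 on the log2 scale with quantile normalization (limma adjusted p = 1). It ranked 7 or 8 from the highest in every library, and this setting gives each rank 1 value. The difference between lines of LIN28A, 0.74, was -0.36 with a pseudocount of 0.01 (limma adjusted p = 0.3995). Its level in line 1 lay under 0.5 FPKM, where the pseudocount weighs most.

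No sign was found that the replicate numbers pair the samples, though 3 libraries per group are too few to exclude it. The deviations of libraries with the same number had correlations from -0.083 to 0.0874, and 1 of 12 libraries correlated best with its own number in every other group. With the number as a block across all groups limma called 7221 genes over both lines, 4154 in line 1, 5500 in line 2 and 225 for the difference between lines, and with a block within each line 7383, 4291, 5709 and 97. For the difference, the block across all groups ended the limma calls of SNORA51 (adjusted p = 0.0686) and SPP1 (0.0840) and the camera call of axon guidance genes (0.0569). The block within lines ended those of GREM1 (0.0528), GNA14 (0.0571), SNORA51 (0.0777), SERPINA3 (0.0695), SPP1 (0.109) and VAT1L (0.0744) and the camera calls of oligodendrocyte markers (0.0610), synaptic genes (0.0598) and axon guidance genes (0.0598). No other call of a named gene, list or class ended with the blocks run for it. The block within lines is nested in the lines and was not run between siCTRL libraries.

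Of 150 named genes called over both lines, 9 lost the call or the direction under some setting besides treat, and 88 lost the call with treat. Besides treat, 12 of 48 genes named for another comparison lost their call there. Of 44 list and class calls by camera, 41 ended with an estimated correlation and 18 under a setting other than that, treat and fry. With fry, 8 of 37 list calls ended. In line 1, line 2 and between siCTRL libraries the real grouping called 4552, 5836 and 10625 genes and the highest other 1, 1 and 0, and 10 groupings, of which 1 reached the real count in each, are too few for a share under 0.05. Over both lines 1 of 100 groupings called as many genes as the real one (7410, highest other 2030). Groupings that mix the siRNAs of a line put the siSF1 effect into the spread, which lowers their counts. The share bears only on these libraries, which may be technical replicates, and does not exclude chance between cultures. If the step of the values is 1 read, a gene at the filter of 0.5 FPKM had 74.9 to 123 reads per kilobase (50.0 at the depth of 100 in the labels), fewest in siSF1 replicate 1 of line 2, so that small changes of low genes are the least certain.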

Other observations

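In this part the test of levels near the floor, the expected number of risers with the let-7 word, the setting without the 2 shallowest libraries, and the choice to count only protein-coding genes among the deepest falls came only after the result was seen, and the word search, with and without genes that hold GAGAACA, was thought of after the fold changes were seen. Besides the genes named so far, PRDX1, a peroxidase that removes hydrogen peroxide, fell by 1.29 on the log2 scale over both lines, MPC1, a subunit of the mitochondrial pyruvate carrier, by 1.27, FDX1, a mitochondrial ferredoxin, by 1.26, and EBPL by 1.22. These 4 genes were chosen after their values were seen, among those at least 2-fold lower in each line, and the 3' UTR of each holds GAGAACA. Of the snoRNA host genes, a list that did not pass, EPB41L4A-AS1 rose by 0.39, ZFAS1 by 0.35 and GAS5 by 0.24, while SNHG9 fell by 0.39. Of the heat shock genes HSPA1A rose by 0.49 and HSPA1B by 0.47, whose reads can be shared, and of the apoptosis regulators PMAIP1, which encodes NOXA and whose 3' UTR holds GAGAACA, fell by 0.41. Neither list passed.

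In line 2 taken by itself, 5 of 6 oligodendrocyte lineage markers fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0230; adjusted p = 0.526 with an estimated correlation). This call ended under 4 of 16 other settings, the estimated correlation included (adjusted p from 0.0514 to 0.526). Of 25 SR proteins and their kinases 12 fell in line 2 and 0 rose, again with the same counts adjusted over the list alone (camera adjusted p = 0.0176; adjusted p = 0.526 with an estimated correlation). The SR list did not pass in line 1 (camera adjusted p = 0.231), and the difference between lines did not pass either (camera adjusted p = 0.128). In both lines 2337 genes were called higher and 2283 lower with all siSF1 libraries beyond all siCTRL libraries of each line. If the libraries were independent, chance would separate 0.5% of genes in this way, or 81.4 genes, called or not. The libraries may be technical replicates, so the higher counts do not exclude chance between cultures.

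The deepest falls besides SF1 may come in part from siRNA seeds that match other mRNAs, which is a hypothesis. GAGAACA, which the SF1 mRNA holds, had the lowest z of 16383 words of 7 bases in 3' UTRs, -24.0 (-21.2 in line 1, -23.5 in line 2), before AGAGAAC with -12.6, and among 10576 genes without GAGAACA the lowest was TTGGACT (-6.75), which the SF1 mRNA holds too, as it holds 17.2% of words. Of 23 genes at least 2-fold lower in each line 18 were protein-coding, all with an annotated 3' UTR, and 13 held GAGAACA where 1.57 are expected (exact Poisson-binomial test, Bonferroni p = 1.2e-08 over 2815 words of the SF1 mRNA). The median siCTRL level of the 23 genes, 9.25 FPKM, argues against noise of low-level genes. What stays open is which falls follow from the loss of SF1 and whether other seeds act, since the siRNAs and the loss of SF1 are in the same libraries and the siRNA sequences are not given in the sources used here.

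Of the 11 named risers with an annotated 3' UTR, 5 (LIN28A, IGDCC3, FIGNL2, DOK3 and CRB2) hold the let-7 word CTACCTC, which might point to lower let-7 activity. Over 12397 genes outside the named risers the word had a z of 0.497, rank 4243 from the highest of 16383, which argues against a general loss of let-7 activity. From 3' UTRs of like length and GC content 1.04 of the 11 are expected to hold it, but the word was chosen after the risers were seen, and corrected over 16383 words the exact Poisson-binomial test gives a Bonferroni p of 1. That test decides nothing, so length and base composition of the 3' UTR stay open, and so does what the 5 risers share besides the word.

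The siSF1 effect was lower for long genes than for short genes. In 5 groups ordered by span, the median over both lines went from 0.0532 in the shortest to -0.0386 in the longest. The longest group had a median of -0.0039 in line 1. Across genes the rank correlation between effect and span was -0.171. Given exonic length it was -0.140 (-0.153 to -0.116 on leaving out each library), which argues against transcript length bias as the whole cause over both lines. It was -0.165 in line 2. In line 1 it was -0.096, which falls just short of the bar set against that bias. Without the 2 shallowest libraries the correlation with span alone was -0.172 over both lines, which argues against their depth as its cause there. Line 1 by itself then had -0.0764, which falls short of the bar set for this, and line 2 had -0.236. Among genes without GAGAACA the correlation was -0.142 given exonic length, so genes that hold the full word are not its only source. Yet among such genes GAACAAA (z -6.33) and TGAACAA (-5.46) still ranked low. Both hold GAACAA, a part of GAGAACAA in the SF1 mRNA, so weaker matches to that seed stay open. The rank correlation with the number of exons, given span and exonic length, was -0.07 (-0.0888 to -0.0571 on leaving out each library). It was -0.0853 in line 2, and both values are as a loss of SF1 acting on introns would give. They are not separate support, since the value over both lines includes line 2. In line 1 it was -0.041, which falls short of the bar set for that explanation. A loss of SF1 acting on introns may be a biological source of only part of the pattern. Span given exonic length and exon number kept -0.101 (-0.0715 in line 1, -0.118 in line 2). This is a hypothesis found and tested on the same data, in which genes are not independent and splicing was not analysed.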
